A study of Arabidopsis lyrata with 12 samples.

How the data were processed

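Young leaves of Arabidopsis lyrata accession MN47 were profiled in 12 libraries. There were 2 libraries each for histone H3 trimethylated at lysine 4 (H3K4me3), H3 trimethylated at lysine 27 (H3K27me3), H3 monomethylated at lysine 27 (H3K27me1) and immunoprecipitated methylated DNA (5-methylcytosine, 5mC). The others were 1 input library for the chromatin precipitations, 2 input libraries for the methylated DNA and 1 mRNA library. Groups were taken from the sample titles. Per the labels, plants grew in soil with 16 hours of light at 22.5 °C, and libraries were made from 20 ng of DNA or 1 µg of total RNA.

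The authors deposited 1 list of enriched domains per mark, each with a scaffold, a start, an end and a whole-number score. Bowtie and SICER are named in the submitters' processing notes, with no version. The window, gap and false discovery settings, the genome build, and whether the replicates were pooled are not given in the sources used here. What the deposited score counts is not stated either. It rose with domain width in each list, and SICER lists commonly hold the reads of a domain in that place. Domain edges fell on a grid of 150 bp for H3K4me3 and 5mC and 300 bp for H3K27me3 and H3K27me1. The authors also deposited, for the mRNA library, a mean exon coverage per gene with the gene's scaffold, start and end. No strand, exon position or gene name stood beside the 24268 genes. No normalization of the coverage is stated, and its lowest value was exactly 1, at which 1998 genes were listed. The mean may therefore have been taken over covered bases alone, or the list limited to genes with reads. Sequencing depth is unknown for all libraries, so no value here was corrected for it. Domain numbers, widths and lengths, genes per mark and coverage can vary with depth and calling settings, which limits comparisons between marks. Input libraries and values per replicate were not used here.

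Coordinates were used as deposited and are printed counting from 1, on the scaffold names of the files. Scaffold lengths were taken as the highest coordinate in any file, which is a lower bound. They came to 205.5 Mb over 630 scaffolds, of which 194.2 Mb lay on the 8 main scaffolds. The RefSeq gene table of assembly v.1.0 (34365 genes) matched 0 of the 24268 gene identifiers. Gene names could not be given, and 13 lists (192 genes) and 9 keyword lists fixed before the data were examined were not tested. Those lists cover photosynthesis, housekeeping, chromatin and DNA methylation machinery, clock and light, defence, immune receptors, leaf epidermis, meristem and organ boundary, floral, root, pollen, seed and imprinted genes. The keyword lists cover ribosomal proteins, transposon-related genes, histones, and MADS-box, homeobox, WRKY, NB-LRR, F-box and cytochrome P450 families.

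The overlap of each pair of marks was counted in base pairs and divided by the mean of 1000 circular shifts of the second mark within each scaffold. The two-sided empirical p of this permutation of positions was adjusted by the Benjamini-Hochberg method over the 6 pairs, and its smallest possible unadjusted value was 0.002. It describes these lists, not replicates. A gene carried a mark when domains covered at least 200 bp of its span, or all of a shorter span. Genes were grouped by their combination of marks, and the median coverage of each group was placed among 10000 random lists with the same numbers of genes per gene-length decile. A percentile outside 2.5 to 97.5 counted as standing apart. This describes 1 library, because genes are not replicates and no replicate check exists for the mRNA values. Shares of genes are given with exact (Clopper-Pearson) 95% intervals, which cover counting error only. Because strand is absent, profiles along genes pool both ends, over 2 kb outside and along the span of genes of at least 1 kb. Ends of 500 bp were compared in genes of at least 2 kb. The windows of 100 kb on the main scaffolds, the windows beside empty stretches, and the neighbouring-gene counts were added after the data were examined.

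The rule for named genes took members of the fixed lists, the 3 longest domains of each mark with their genes, and the 3 genes with the highest mRNA value in each combination with at least 100 genes. Because the files pair no identifier with a name, only 2 genes with H3K4me3 alone and 2 with H3K27me3 alone are printed, those with the highest coverage.

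The overlap and list procedures were tested on simulated data. Of 40 pairs of independent lists of 10000 domains, 1 was called different, and all 10 pairs sharing 2% of domains were called enriched. These domains had equal widths and were placed evenly at random on the main scaffolds. The clustering, range of widths and empty stretches of the deposited lists were not simulated, so error rates under them stay unknown. Of 40 unchanged lists of 200 genes among 24268, 2 lay outside the central 95%, and of 40 lists raised 1.5-fold, 36 lay above it. The shuffles used for intervals between genes found 0 of 40 simulated sets without an effect and 40 of 40 with a 1.5-fold effect, at 16000 intervals each. Those used for genes with and without 5mC found 0 of 40 sets without a difference and 40 of 40 with a log2 difference of 1, at 708 genes each. Simulated interval and gene values were drawn independently, so likeness of neighbours was not simulated. For the gene lists, coverage was permuted over all genes, which removed any relation to gene length. Fewer shuffles and random lists were run than on the data. Error rates on the deposited values thus stay unknown here too.

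Alternatives set before the data were examined were the top 50% of domains by score, merging of domains under 600 bp apart, the main scaffolds alone, uniform random placement, domains covered to at least 50%, base pairs inside listed genes, overlaps of 1 bp or 50% of a gene, and mean log2 values with a pseudocount of 1 or 0.1. Inside listed genes, the kept base pairs were joined end to end and moved by 1 shift across all scaffolds. The later set without empty windows was treated alike, so both settings changed the shifts as well as the base pairs. Counts, lengths and ratios without a test were called moved beyond 1.5-fold. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.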

Results

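The data describe where 3 histone H3 methylation marks and DNA methylation lay along the genome of young Arabidopsis lyrata leaves, and how much mRNA the genes beneath them gave. H3K4me3 is known from the 5′ part of transcribed plant genes and H3K27me3 from genes held silent by Polycomb complexes. H3K27me1 and cytosine methylation (5mC) are known from transposons and heterochromatin. The values below come from 1 domain list per mark, for which 2 libraries were sequenced, and from the mean exon coverage of 24268 genes in 1 mRNA library. No replicate error could therefore be attached to any of them. Depth is unknown for every library, and differences between marks in domains or genes were not corrected for it.

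H3K4me3 lay almost wholly in listed genes, whereas the other 3 marks lay mostly outside them. Genes that the mRNA table does not list count as outside here. Of the base pairs in H3K4me3 domains, 91.3% fell inside listed genes, which made up 31.5% of the scaffold extent. The share was 22.0% for H3K27me3, 9.21% for H3K27me1 and 8.37% for 5mC. The H3K4me3 list held 21676 domains with a median width of 750 bp (quartiles 600 and 1050 bp) and covered 17.9 Mb. The H3K27me3 list held 19060 domains (median 900 bp, quartiles 600 and 1800 bp) over 26.6 Mb, and the H3K27me1 list 17702 domains (median 1200 bp, quartiles 600 and 2100 bp) over 34.8 Mb. 5mC had the most domains, 33531, with a median of 600 bp (quartiles 300 and 1500 bp) over 44.4 Mb. Domains wider than 5 kb made up 30.8% of the H3K27me1 length, 29.4% of the 5mC length and 11.7% of the H3K27me3 length, and there were 0 such H3K4me3 domains. With the top 50% of domains by score, H3K4me3 covered 11.6 Mb. Score rose with width (Spearman 0.860 for H3K4me3), so this choice favours wide domains.

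The widest H3K4me3 domain, 4.5 kb on scaffold 3 (9981001 to 9985500), lay over 1 listed gene with a coverage of 55.9. The widest H3K27me3 domain, 22.8 kb on scaffold 3 (12693301 to 12716100), touched 0 listed genes. The next H3K27me3 domains, of 18.6 and 18 kb, stood side by side on scaffold 1 between 14193301 and 14230200 and also touched 0 listed genes. The widest 5mC domain, 51 kb on scaffold 3 (18165301 to 18216300), had 0 listed genes. The widest H3K27me1 domain measured 136.2 kb at the end of scaffold 3 (24306901 to 24443100) and held 12 listed genes, with a median coverage of 95.7.

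H3K27me1 and 5mC shared most of their territory, and H3K4me3 was set apart from both. They overlapped over 27.3 Mb, 3.36 times the shifted mean (adjusted permutation p = 0.003), which was 78.4% of H3K27me1 and 61.5% of 5mC. H3K4me3 overlapped H3K27me1 at 0.108 and 5mC at 0.118 of the shifted mean. Its overlap with H3K27me3, 1.28 Mb, was 0.545 of the shifted mean (adjusted permutation p = 0.003 for each of these pairs). Across the alternatives these 4 ratios kept their side of 1 but moved widely, that of H3K27me1 with 5mC to 10.2 inside listed genes. There the 2 marks covered only 4.95 and 5.73% of base pairs, against 17.0 and 21.6% of the extent, which lets a ratio rise. It does not mean that more was shared in genes. Of base pairs under these 2 marks and no other, 6.60% lay in listed genes, against 17.3% under H3K27me1 alone and 9.95% under 5mC alone. H3K27me3 lay in H3K27me1 domains 1.04 times as often as after shifts (adjusted permutation p = 0.138) and in 5mC domains 1.07 times (adjusted p = 0.0192). Both ratios moved either way with the setting. They were 1.14 and 1.198 with uniform placement, 1.28 and 1.37 for domains covered to at least 50%, and 1.32 and 1.56 inside listed genes (adjusted permutation p = 0.002 for each). With the top 50% of domains by score, a choice that favours wide domains, they were 0.813 and 0.822, both called lower than the shifts (adjusted permutation p = 0.002). An alternative added after the data were seen left out the 100-kb windows that hold no domain or gene. There the ratios were 0.923 (adjusted permutation p = 0.024) and 0.976 (adjusted permutation p = 0.422), so the call for H3K27me3 and 5mC was lost. Inside listed genes and without empty windows, the shifts ran over all kept base pairs joined, not within each scaffold. These changes thus cannot be put down to the base pairs alone.

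The 15105 5mC domains that touched H3K27me1 had a median width of 1500 bp and covered 34.7 Mb, while the 18426 others had a median of 300 bp and covered 9.75 Mb. A wide domain touches another more readily by its width alone, and 5mC domains that touched H3K27me3 (1050 against 600 bp) or H3K4me3 (1200 against 600 bp) were wider too. Among H3K27me1 domains, 85.5% touched 5mC. The 2572 that did not touched a listed gene in 41.3% of cases, against 9.54% for those with 5mC.

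H3K4me3 was the mark found in the most listed genes. It covered at least 200 bp of 19097 genes (78.7%, interval 78.2 to 79.2%). H3K27me3 was found in 4164 genes (17.2%), 5mC in 2668 (11.0%) and H3K27me1 in 1935 (7.97%), and 22207 genes had at least 1 mark. These counts depended on the rule: with domains over at least 50% of the span they were 5742, 2619, 831 and 757 genes. With the top 50% of each list by score, 11140 of the 24268 genes had H3K4me3, 1751 had 5mC and 904 had H3K27me1. All these shares are of listed genes alone. Genes without reads may be missing from the list, so shares over all genes may differ.

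Genes with H3K4me3 alone had the highest mRNA coverage of the groups, and genes with H3K27me3 or H3K27me1 but no H3K4me3 had the lowest. The 15362 genes with H3K4me3 alone had a median coverage of 10.2 (quartiles 5.31 and 20.9), and the 1050 with H3K4me3 and 5mC a median of 9.77. Both medians lay above all 10000 random lists (percentile 100). The 1707 genes with H3K27me3 alone had a median of 1.32, the 357 with H3K27me1 alone 1.47, the 350 with H3K27me1 and 5mC 1.26, and the 253 with H3K27me3, H3K27me1 and 5mC 1.14. The 2061 genes without any domain reached 2.02 and the 216 with 5mC alone 1.85. Among genes with H3K4me3 and H3K27me1, the 297 that also had 5mC lay between, with a median of 5.03. The 411 that did not had a median of 2.05, close to the genes without any domain. All of these lay below every random list (percentile 0). The random lists drew on all listed genes, of which 63.3% had H3K4me3 alone. For groups without H3K4me3, the percentile thus does not tell the other marks from the lack of H3K4me3. Differences among the low groups were not tested. The lowest medians sat near the floor of the table: 37.1% of the genes with H3K27me3 alone, 28.6% with H3K27me1 alone and 41.1% with H3K27me1 and 5mC were listed at exactly 1. Without genes at exactly 1, an alternative added after the data were seen, these medians were 2.01, 1.91 and 2.03, with 1.81 for H3K27me3, H3K27me1 and 5mC and 3.05 for 5mC alone, still below every random list. In that alternative, genes with H3K4me3 and H3K27me1 but no 5mC had a median of 2.24, below the 2.64 of genes without any domain. At 50% of the span, the group without any domain grew to 15439 genes with a median of 6.95, and H3K4me3 alone had a median of 15.5 in 5197 genes, both on the same side of their random lists. The group with H3K4me3 and 5mC shrank to 59 genes and no longer stood apart (median 8.64, percentile 90.3), and the one with H3K27me1 besides shrank to 11 genes with a median of 6.37, near the middle of its random lists (percentile 59.3).

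**Figure D1:**
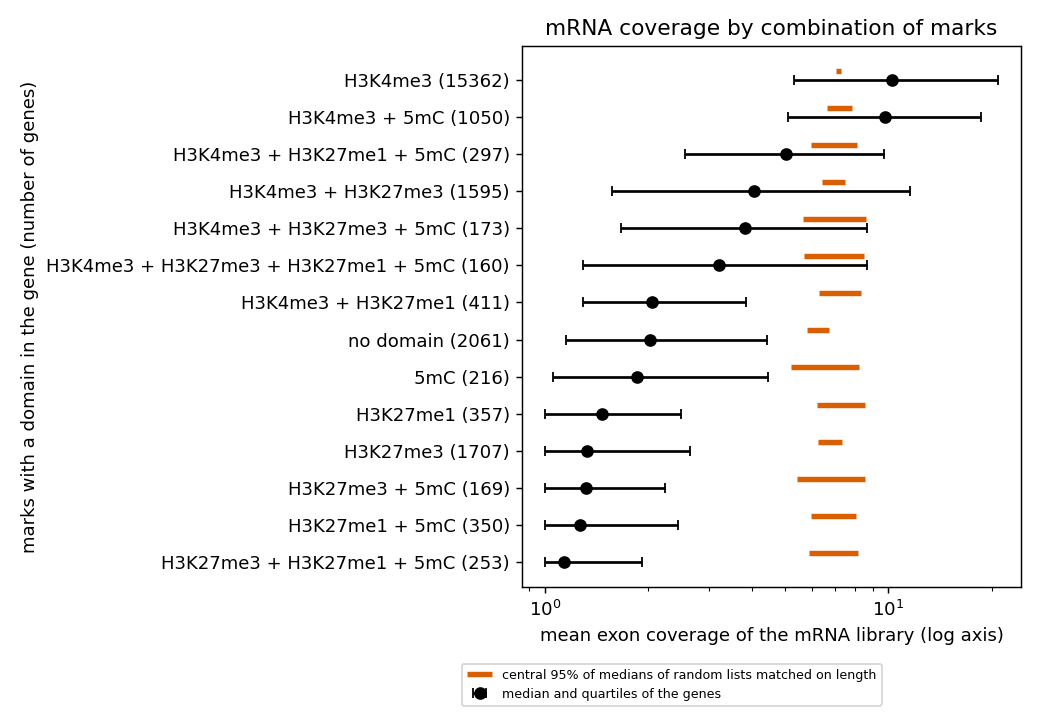
Median mean exon coverage (points, log axis) with quartiles (bars) for each combination of marks found in at least 100 genes, with the number of genes in brackets. The orange lines give the central 95% of medians of random lists matched on gene length. H3K4me3 alone (10.2) and H3K4me3 with 5mC (9.77) lie above their random lists and the other groups below.

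Genes with both H3K4me3 and H3K27me3 lay between the groups with either mark alone. The 1595 genes with both marks had a median coverage of 4.06 (quartiles 1.56 and 11.6), below every random list. In 1321 of them (82.8%) the domains shared at least 150 bp inside the gene, and the median was 3.75. In the 274 with domains side by side it was 5.17. Over quartiles of the share of the span under H3K27me3, from the smallest to the largest, the medians were 5.89, 3.94, 3.25 and 2.93. The differences between these groups were not tested. With domains over at least 50% of the span, 442 genes had both marks, with a median of 5.50 that no longer stood apart (percentile 13.3).

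Read from the mRNA side, H3K4me3 was found in 22.0% of the 1998 genes listed at exactly 1 (interval 20.2 to 23.9%) and in 95.9% of the highest quintile of the others (interval 95.3 to 96.5%). H3K27me3 went the other way, from 53.6% (interval 51.3 to 55.8%) to 7.30% (interval 6.55 to 8.10%). H3K27me1 was found in 23.9% and 1.86% of these groups, and 5mC in 21.9% and 7.00%. H3K27me3 reached 7.03% in the fourth quintile, within the interval of the highest.

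**Figure D2:**
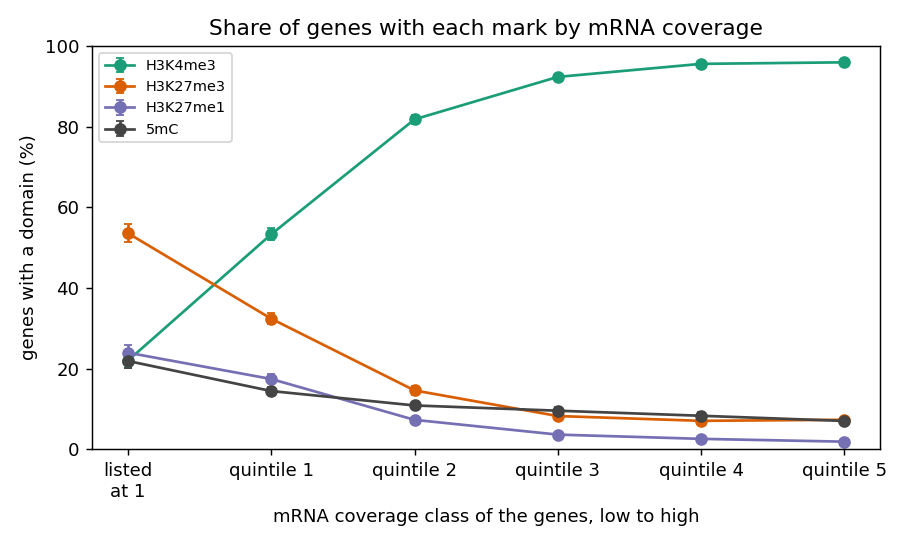
Share of genes with a domain of each mark (y axis, %) in genes listed at a coverage of 1 and in quintiles of the others (x axis), with exact 95% intervals. H3K4me3 runs from 22.0% to 95.9% and H3K27me3 from 53.6% to 7.30%.

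Single genes did not all follow their group. Among genes with H3K4me3 alone, AL4G29210 (scaffold 4, 16321653 to 16322667) and AL1G42730 (scaffold 1, 13187266 to 13188295) had the highest coverage, 27356 and 22395. Both spans lay wholly inside H3K4me3 domains. Among genes with H3K27me3 alone, the highest were AL6G37070 (scaffold 6, 11798246 to 11799516) and AL6G37080 (scaffold 6, 11799272 to 11801066), whose spans overlap. Their coverage was 4708 and 3795, against the group median of 1.32, although 100% of each span lay in an H3K27me3 domain.

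H3K4me3 sat at one end of a gene and seldom at both. Among 13953 genes of at least 2 kb, 10384 (74.4%, interval 73.7 to 75.1%) had it within 500 bp of one end and 438 at both ends, 0.193 times the 2272 that independent ends would give. H3K27me3, H3K27me1 and 5mC were found at both ends of 694, 186 and 261 genes, 5.76, 7.68 and 6.75 times as often as independent ends would give. They too lay more often at one end alone, in 1205, 791 and 947 genes. These 3 marks were rare at ends (9.49, 4.16 and 5.31% of left ends, against 40.4% for H3K4me3). A rarer mark can reach a higher ratio, so the ratios are not comparable in size with that of H3K4me3. With ends of 1000 bp, an alternative added after the data were seen, H3K4me3 was at both ends of 940 genes.

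H3K4me3 coverage was highest inside the gene, not at its edge. Over 21518 genes of at least 1 kb it averaged 37.6% between 10 and 15% of the span from an end and 23.3% in the middle, against 10.6% in the 200 bp outside. In the middle of genes it was 42.9% for the highest mRNA quartile and 10.8% for the lowest. 5mC averaged 4.58% in the middle of genes, 5.87% just outside and 11.6% near 2 kb outside. H3K27me3 averaged 9.91% in the middle of genes, 4.98% just outside and 11.5% near 2 kb outside. In the middle of the lowest mRNA quartile of genes it averaged 25.5%, against 3.65% in the highest.

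**Figure D3:**
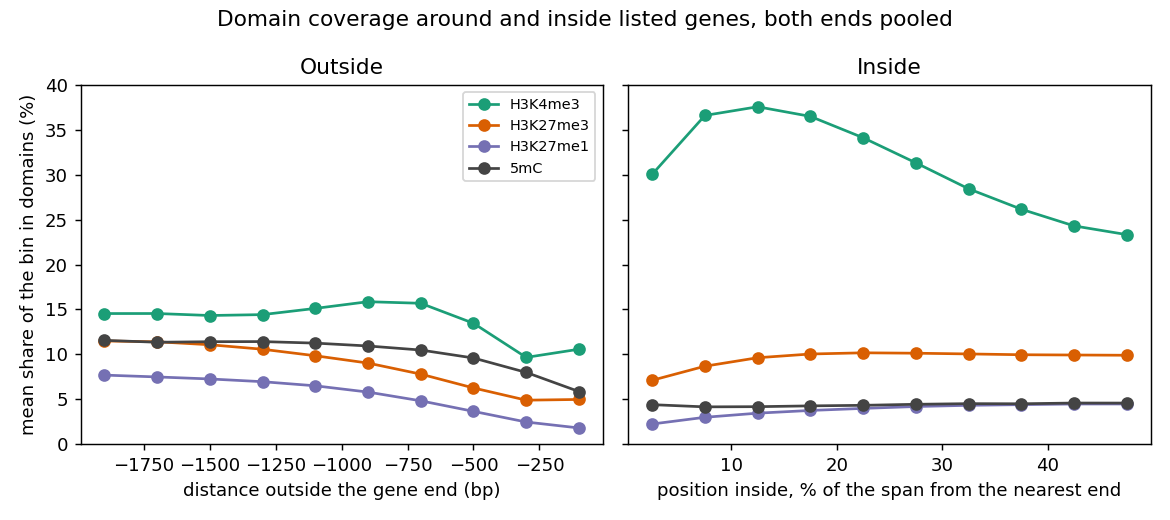
Mean share of each bin inside domains (y axis, %) outside gene ends in bins of 200 bp (left) and inside, in bins of 5% of the span counted from the nearest end (right), for 21518 genes of at least 1 kb. Both ends are pooled because strand is absent, and H3K4me3 peaks at 37.6% inside the gene.

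Along the main scaffolds, H3K27me1 and 5mC gathered where listed genes were few. Gene base pairs count listed genes alone here, so windows poor in them may hold unlisted genes. Over quartiles of 100-kb windows, from the fewest gene base pairs to the most, H3K27me1 coverage averaged 32.5, 19.1, 11.1 and 5.78%, and 5mC 41.3, 26.5, 15.7 and 8.04%. H3K4me3 averaged 3.46% and 16.5% in the lowest and highest of these quartiles. H3K27me3 was highest in the second quartile, at 17.8%, and lowest in the most gene-rich, at 10.2%. With windows of 50 kb, an alternative added after the data were seen, the first quartile was the highest, at 17.6%. Its densest window, on scaffold 7 (15100001 to 15200000), was covered to 85.6% and held 0% listed gene, and the window before it was covered to 70.9%. Across the 1772 windows, which are not independent replicates, the Spearman correlation of H3K27me1 and 5mC was 0.957.

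Each of the 8 main scaffolds had 1 long stretch of 1.5 to 2.8 Mb without any domain or listed gene. These stretches held 166 of the 167 empty windows. In the 160 windows within 1 Mb of them, H3K27me1 averaged 39.0% and 5mC 45.3%, against 10.4% and 14.4% in windows at least 5 Mb away, and both were higher near the stretch on 8 of 8 scaffolds. H3K4me3 averaged 2.91% near and 13.2% far, and was lower near on all 8. H3K27me3 averaged 8.59% near and 14.1% far, but was higher near on 2 scaffolds. What the stretches hold was not analysed here.

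**Figure D4:**
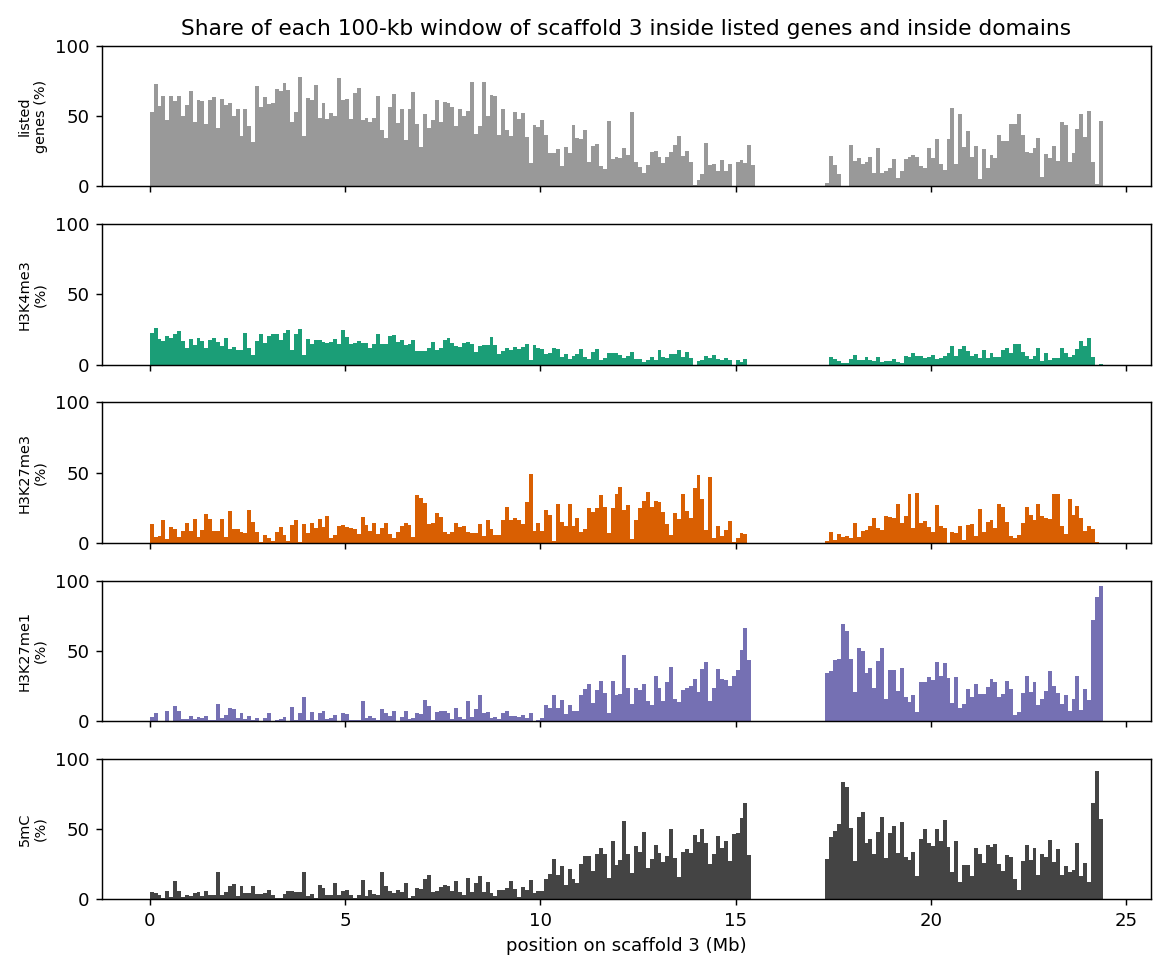
Share of each 100-kb window of scaffold 3 (x axis, Mb) inside listed genes and inside domains of each mark (y axes, %). H3K27me1 and 5mC are high beside the empty stretch from 15500001 to 17300000 and at the right end of the scaffold, where listed genes are few or H3K4me3 is low.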

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

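All tests in this part were chosen after the values were seen. In 1 of the lists the highest score stood far from the rest. The H3K27me1 domain at the end of scaffold 3 (24306901 to 24443100) had a score of 579041, 8.27 times the next highest, and held 5.23% of the summed score of its list. The highest score was 1.10, 2.49 and 1.54 times the next for H3K4me3, H3K27me3 and 5mC.

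Over all H3K27me1 domains the median score per base pair was 0.212, and 72 domains lay more than 10 times above it. Inside the scaffold 3 domain it was 4.25, and there were 0 H3K4me3 and 0 H3K27me3 domains. Ordinary H3K27me1 chromatin with little mRNA was argued against: the 12 listed genes inside had a median coverage of 95.7, while random lists of 12 of the 1923 other H3K27me1 genes lay between 1.07 and 4.09 (central 95%). The 12 values, from 64.0 to 122.8, were also alike, with a log2 standard deviation of 0.27 against a median of 1.78 over 23625 runs of 12 neighbouring genes, and 1 run, this one, was as even. Reads from DNA present in many copies remain a candidate explanation that these values could not decide. The 8 5mC domains inside also had a raised score per base pair, with a median 4.46 times that of all 5mC domains. The territory that H3K27me1 and 5mC shared concerns coverage and not score per base pair. The median 5mC score per base pair was 1.15 in domains that touched H3K27me1 and 1.09 in the others. Whether dense 5mC accompanies dense H3K27me1 without many copies was not tested. No biological explanation was tested, and the sequence and the input libraries were not used here.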

How the results depend on the processing

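The set without the scaffold 3 domain, the genes at exactly 1, the ends of 1000 bp, the windows of 50 and 200 kb and the empty windows were chosen after the data were seen. Under each alternative run for them, the overlap ratios of H3K4me3 with H3K27me3 (0.185 to 0.796), H3K27me1 (0.0189 to 0.180) and 5mC (0.0611 to 0.246), and of H3K27me1 with 5mC (3.33 to 10.2), kept their side of 1 and of the threshold. H3K27me3 with H3K27me1 was 0.813 for the top 50% of domains, 1.14 for uniform placement, 1.28 for domains covered by at least 50%, 1.32 inside listed genes and 0.923 without empty windows. H3K27me3 with 5mC was 0.822 (a call in the other direction), 1.198, 1.37, 1.56 and 0.976 (no call) under the same settings. The top 50% of H3K4me3 domains covered 11.6 Mb, and the top 50% of each list left 11140 genes with H3K4me3, 904 with H3K27me1 and 1751 with 5mC. At 50% of the span 5742, 2619, 757 and 831 genes had H3K4me3, H3K27me3, H3K27me1 and 5mC. At 50%, median coverage was 5.50 with H3K4me3 and H3K27me3, 8.64 with H3K4me3 and 5mC, and 6.37 with H3K4me3, H3K27me1 and 5mC (11 genes). With H3K4me3, H3K27me3 and 5mC it was 19.8 (7 genes, percentile 95.8), against 3.81 (percentile 0) in the main setting, a change of side. With all 4 marks it was 3.06 (3 genes, percentile 26.1), against 3.20 (percentile 0). The other 79 comparisons of coverage with random lists kept their direction and call, though at 50% of the span the median was 6.95 without any domain and 15.5 with H3K4me3 alone, and without genes at exactly 1 the median rose by over 1.5 times for H3K27me3 alone (2.01), H3K27me1 and 5mC (2.03), H3K27me3, H3K27me1 and 5mC (1.81), 5mC alone (3.05) and all 4 marks (4.98). H3K4me3 lay at both ends of 940 genes with ends of 1000 bp. For all of these, the cause was not tested. No paired analysis was possible because 1 list stands for each mark, so no replicate could be left out or blocked. Not run, for want of strand, names, exon lengths or values of 0, were the transcription start, transposon, length, gene list and zero-value alternatives. Depth is unknown, so how far it limits these values could not be given.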

Other observations

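All tests in this part were chosen after the results were seen. Genes with H3K27me3 lay beside one another more often than a shuffle of the marks along each scaffold gave. The shuffles spread each mark over a whole scaffold, so gathering of a mark in part of a scaffold can raise the ratios below. They cannot tell such gathering from likeness of direct neighbours. Of 23329 neighbouring pairs on the main scaffolds, 1171 had H3K27me3 in both genes, 1.69 times the mean of 1000 shuffles, whose highest was 773. In 1063 of these pairs no single domain joined the genes. The longest run, 14 genes on scaffold 5 (2135234 to 2240248), had a median mRNA coverage of 2.32. The ratio was 1.73 for 5mC, with a longest run of 11 genes on scaffold 7 (20975795 to 21061861, median coverage 1.86). It was 1.98 for H3K27me1, whose longest run is the 12 genes inside 1 domain at the end of scaffold 3. No single domain joined 374 of the 446 5mC pairs and 239 of the 294 H3K27me1 pairs. For H3K4me3 the ratio was 1.02 over all pairs (14921, highest shuffle 14733). The 14326 pairs that no single domain joined came to 0.979 of the shuffle mean for all pairs. The shuffles held no such removal, so this last value is lowered and has no match in them. The longest H3K4me3 run held 46 genes on scaffold 3 (3733381 to 3900878).

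Of the 10 5mC domains on the main scaffolds with the highest score per base pair, 4 lay within 10 kb of an end, where 30 of all 31326 domains (0.0958%) were found. The other 6 lay over 1 Mb away, and a right end is only the highest coordinate in any file, which such a domain can itself set. The highest, on scaffold 4 (23327551 to 23328300), stood 32.0 times above the median of the list.

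Gene identifiers on the main scaffolds run in steps of 10, and 8100 numbers between listed genes are skipped. In intervals of 3 to 10 kb between listed genes, H3K27me3 covered 9.53% where no number was skipped (3244 intervals), 24.1% with 1 skipped (1506 intervals) and 36.0% with 2 (416 intervals). Interval length as the cause was argued against, since at matched length H3K27me3 coverage was 2.82 times higher with a skipped number and shuffles gave 0.910 to 1.09. A rise of all marks where genes are sparse was argued against too, since the same ratio was 0.695 for 5mC and 0.711 for H3K27me1, although it was 1.28 for H3K4me3 (highest shuffle 1.16). Coverage with 2 or more skipped numbers was 1.60 times that with 1, above every shuffle (highest 1.12), which is consistent with unlisted genes that carry H3K27me3 and had no reads in this library, a hypothesis that an annotation with these identifiers, not used here, would test.

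Genes with H3K4me3 and H3K27me1 had lower mRNA coverage without 5mC than with it. The 411 genes without 5mC had a median coverage of 2.05 and the 297 with it 5.03, while H3K4me3 genes without H3K27me1 differed by a log2 of only -0.07 (9.77 with 5mC, 10.2 without). Gene length as the whole cause was argued against, as the log2 difference over length quartiles was 1.18, above every one of 1000 shuffles (highest 0.43). The share of the gene under H3K27me1 was argued against in the same way, with a difference of 1.14 over its quartiles (highest shuffle 0.43). What else sets these genes apart stays open, no biological explanation was tested, and the values rest on 1 mRNA library.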
